A study of Mus musculus with 47 samples.

How the data were processed

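RNA was sequenced from OT-I CD8 T cells, mouse T cells whose transgenic T cell receptor recognises an ovalbumin peptide. Per the labels, CD8-enriched OT-I spleen cells on a Rag-deficient background were pre-incubated for 30 min without or with PRN-694, an inhibitor of the Tec-family kinases ITK and RLK, whose dose the protocol gives as 50 nM "or otherwise noted". They were then cultured with congenic wild-type splenocytes that had been loaded for 60 min with the ovalbumin peptide N4, the altered peptide T4 or no peptide. The altered peptide T4 is a ligand of lower potency for this receptor. OT-I cells were sorted on CD8a, CD45.2 and a viability dye, and libraries were made from small numbers of cells by template switching and transposase tagging. The labels give no peptide concentrations.

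The deposited files were 3 tables, 1 per replicate number, with 23845 gene symbols in each. Per the processing notes deposited with the series, the authors trimmed reads with Trimmomatic 0.38, aligned them with Bowtie2 2.3.2, quantified them with RSEM 1.2.29 on build mm10 and used DESeq2 1.26.0. The values of the deposited tables are a score per gene, namely TPM (transcript abundance scaled to a common library total) rounded to whole numbers. The column totals lay between 999680 and 999875, and the smallest value above 0 was 1. Read totals are not in the files, so the depth of each library is unknown, and neither counting intervals nor detection limits can be given. A value of 0 is reported as listed at 0, since it covers everything below the rounding limit.

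The 47 libraries fell into 16 groups by time, peptide and inhibitor, 15 with 3 libraries and 1 with 2 (N4 with PRN-694 at 120 min, replicates 2 and 3). The column for 120 min, N4 and PRN-694 in the replicate 1 table matches no listed sample and was left out. The replicate number was taken from the table that holds the column. Whether the numbers pair the samples was checked by correlating libraries after removing group means: the median Pearson r was 0.611 over the 345 pairs of libraries that share a number and -0.34 over pairs that do not, and each of the 47 libraries correlated best with a library of its own number. Nothing in the labels says that the replicates came from separate animals, so the p-values measure only the spread between these samples.

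The test, the filter, the comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Values were analysed as log2(TPM + 1). Genes with a mean of at least 1 TPM in at least 1 group were tested, 11757 in all. Linear models were fitted to all 47 libraries with limma 3.58.1 in R 4.3.3, with a term per group and moderated variances (trend and robust options). The 21 comparisons were N4 against unstimulated, T4 against unstimulated, N4 against T4, PRN-694 against no inhibitor with each peptide, and the difference between the inhibitor's effects with T4 and with N4 (the interaction), each at 30, 60 and 120 min, together with unstimulated co-cultures at each time against 0 min. P-values were adjusted by the Benjamini-Hochberg method over the 11757 genes of each comparison, and genes with an adjusted p below 0.05 are those said to rise, fall or pass. All tests were two-sided. The fixed design had no term for the replicate number. Since the numbers proved to pair the samples, values from the same model with the number as a block are given beside the results, as counts or p-values "in the blocked model".

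The 21 gene lists, written from general knowledge, were immediate early transcription factors, MAP kinase feedback regulators, NF-kB pathway targets, NFAT-linked targets, cytokines and chemokines, activation and co-receptor surface molecules, quiescence and naive T cell genes, effector differentiation transcription factors, ribosome biogenesis, nutrient uptake and metabolism, cytotoxic effector genes, T cell receptor signalling components, interferon-stimulated genes, heat shock and proteotoxic stress, CD8 T cell identity, housekeeping genes, and markers of B cells, of myeloid and dendritic cells, of CD4 T cells, of NK cells and of erythroid cells. Lists share some members. Each was tested against the other genes with camera (limma) at its preset inter-gene correlation of 0.01, with p-values adjusted over the lists of a comparison, and again with a correlation estimated from the data. Genes induced by a peptide at a time were also tested as a list under PRN-694 with the other peptide, and these 6 lists, chosen on these libraries, were adjusted among themselves. Counts of list members that pass are also given adjusted over the list alone.

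Named genes are the 6 with the highest and the 6 with the lowest log2 change among those that passed, with a mean of at least 5 TPM in a compared group and no overlap between the libraries of the groups (predicted genes, pseudogenes and small RNAs passed over), a panel of 26 genes of T cell activation, and up to 4 members per list with the smallest adjusted p. Coordinates come from GENCODE vM21 on GRCm38 (mm10), which holds 11265 of the tested symbols.

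Alternatives were pseudocounts of 0.1 and 5, no filter, median-ratio scaling of the TPM, the replicate block, only the libraries of the groups compared, each library left out, each replicate number left out, and the estimated correlation. The block with median-ratio scaling and the block with the estimated correlation were added after the data were seen. Other splits of the libraries into groups of the same sizes were fitted for the comparisons with 3 libraries per group. The procedure was also tested on simulated values, in which the real differences between the compared groups were absent and a small share of genes was given changes of known size.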

Results

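RNA levels of 23845 genes were measured in 47 libraries of sorted OT-I CD8 T cells, 3 taken before co-culture (0 min). The other 44 were taken after 30, 60 or 120 min with splenocytes that carried no peptide, N4 or T4. Cultures with N4 or T4 were without or with PRN-694, and those with no peptide were without it. Each of the 16 groups held 3 libraries, except N4 with PRN-694 at 120 min, which held 2. Column totals lay between 999680 and 999875 TPM because the values are scaled, and the read depth is unknown. A mean of 11116 ± 136 genes (SD, n = 3) was listed above 0 at 0 min, and 10102 ± 154 (SD, n = 3) after 120 min with N4. The 10 most abundant genes held 12% of the TPM at 0 min and 15.6% after 120 min with N4. Levels below are mean TPM ± SD, with n = 3 per group unless another n is given, and log2 changes are differences of mean log2(TPM + 1) ± SE from limma. Outside the interaction, each gene given with an adjusted p below 0.05 moved in its stated direction in every replicate pair of its comparison. There were 3 pairs or, for PRN-694 with N4 at 120 min, 2. Pairs were not examined for the interaction.

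The comparison of N4 with unstimulated co-cultures asks which transcripts the strong peptide changes, and when. At 30 min the inflammatory cytokine gene Tnf stood at 717 ± 70.5 TPM with N4 against 1.67 ± 0.577 without peptide, a log2 change of 8.09 ± 0.295 (adjusted p = 2.89e-21). Egr2, a transcription factor gene induced by receptor signalling, rose from 14.3 ± 10.5 to 2790 ± 1340 TPM, a log2 change of 7.65 ± 0.756 (adjusted p = 3.72e-09). The chemokine gene Ccl4 rose from 50 ± 19.3 to 5840 ± 1660 TPM. The gene of the NF-kB regulator IkB-NS, Nfkbid, rose from 50.7 ± 26.3 to 1960 ± 101 TPM. Of the 26 tested immediate early transcription factors, 18 rose and 0 fell (camera adjusted p = 2.71e-89, and 22 rose adjusted over the list alone). Fos, an AP-1 subunit gene, stood at 2370 ± 468 against 31.3 ± 7.23 TPM. In the NFAT-linked list 12 of 22 members rose and 0 fell (camera adjusted p = 2.65e-66, 14 adjusted over the list alone). Among cytokines and chemokines 11 of 23 rose and 0 fell (camera adjusted p = 1.1e-55, 12 adjusted over the list alone). Of the NF-kB pathway targets 8 of 24 rose and 0 fell (camera adjusted p = 1.31e-31, 11 adjusted over the list alone). Among 15 MAP kinase feedback regulators 3 rose (camera adjusted p = 2.48e-07, 7 rose and 2 fell adjusted over the list alone). They included Dusp6, an ERK phosphatase gene, at 62 ± 10.6 against 9 ± 2.65 TPM, and Spry1, an inhibitor of receptor signalling, at 3.33 ± 1.15 TPM and listed at 0 without peptide. Cd69, an early activation marker, rose from 485 ± 316 to 8220 ± 2640 TPM. Among the genes that fell were Txnip, a glucose-responsive arrestin, at 41.3 ± 6.66 against 186 ± 32.7 TPM, and its relative Arrdc3 at 3.67 ± 1.53 against 18.3 ± 8.5 TPM.

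In all, 108 genes rose and 71 fell at 30 min, 179 together. The median of all tested genes lay at -0.16 on the log2 scale, and after median-ratio scaling, which sets that median near 0, 161 rose and 41 fell. In the blocked model 328 rose and 647 fell, but with the block and median-ratio scaling 525 rose and 275 fell. B cell markers, which presenting splenocytes carry, lay 0.85 higher by median with no member passing (camera adjusted p = 2.28e-05, adjusted p = 0.231 with an estimated correlation). The other 5 lists named above kept adjusted p-values between 2.97e-11 and 0.00585 with an estimated correlation.

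After 60 min with N4, Ccl4 stood at 21100 ± 4450 TPM against 33 ± 9.54, and the chemokine gene Ccl3 1580 ± 581 against 1 TPM in each library, a log2 change of 9.56 ± 0.575 (adjusted p = 3.96e-15). Il2, the gene of the T cell growth factor interleukin-2, stood at 118 ± 43.6 TPM and was listed at 0 in each unstimulated library (adjusted p = 1.6e-14). Irf4, a transcription factor whose level follows receptor signal strength, rose from 4 ± 2 to 211 ± 41 TPM. S1pr1, the receptor gene for exit from lymphoid tissue, fell from 831 ± 172 to 31.7 ± 8.96 TPM, a log2 change of -4.68 ± 0.409 (adjusted p = 5.62e-11). Its activator Klf2 fell from 171 ± 87.5 to 10.3 ± 1.53 TPM and the homing receptor gene Ccr7 from 2040 ± 790 to 107 ± 53.1 TPM. Of the 26 quiescence and naive T cell genes 16 fell and 2 rose (camera adjusted p = 1.18e-06, adjusted p = 0.056 with an estimated correlation, 17 fell and 2 rose adjusted over the list alone). NFAT-linked targets rose in 19 of 22 cases, cytokines and chemokines in 16 of 23, and immediate early factors in 21 of 26 with 1 lower. Adjusted over the list alone 20, 17 and 21 of them rose and 0, 2 and 1 fell. Each call was also made with an estimated correlation (adjusted p of at most 4.76e-06). Among 23 activation and co-receptor surface molecules 12 rose and 1 fell (camera adjusted p = 2.73e-15, adjusted p = 0.00815 with an estimated correlation). They included Il2ra, the interleukin-2 receptor alpha chain, at 26.3 ± 11.2 against 3 ± 1 TPM.

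At 120 min with N4, Ccl4 reached 60300 ± 7960 TPM against 35.7 ± 12.7, and Xcl1, a chemokine gene, 9370 ± 5160 against 8.67 ± 4.04. Il2 stood at 912 ± 322 TPM and was listed at 0 without peptide. The co-stimulatory receptor gene Tnfrsf9 rose from 2.67 ± 2.08 to 377 ± 46.1 TPM. S1pr1 fell to 3 ± 1 TPM against 686 ± 167, a log2 change of -7.42 ± 0.409 (adjusted p = 7.85e-17). Pik3ip1, an inhibitor of PI3 kinase, fell to 2.33 ± 1.53 against 247 ± 25.2 TPM. Egr2 stood at 480 ± 210 TPM, still above 15 ± 7.81 without peptide. All 30 ribosome biogenesis genes rose, by a median of 2.21 on the log2 scale (camera adjusted p = 3.27e-26, adjusted p = 1.86e-04 with an estimated correlation), among them Nolc1, a nucleolar phosphoprotein gene, at 330 ± 19.7 against 36.7 ± 2.52 TPM. Genes of nutrient uptake and metabolism rose in 18 of 24 cases and fell in 0 (camera adjusted p = 1.38e-12, adjusted p = 1.86e-04 with an estimated correlation). Of the quiescence and naive T cell genes 22 of 26 fell and 1 rose (camera adjusted p = 2.45e-06, adjusted p = 0.0643 with an estimated correlation). Among 14 cytotoxic effector genes 6 rose and 3 fell (camera adjusted p = 3.96e-04, adjusted p = 0.0193 with an estimated correlation), with the granzyme gene Gzmb at 101 ± 22.1 against 16.7 ± 1.15 TPM. The genes of both kinases that PRN-694 inhibits were lower than in unstimulated cultures. Itk stood at 395 ± 127 against 805 ± 136 TPM (adjusted p = 0.00238), and Txk, which encodes RLK, at 48.7 ± 17.6 against 268 ± 83.3 TPM (adjusted p = 1.58e-04). Itk rose over time without peptide, as given below, and its mean with N4 was above that at 0 min.

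The 26 T cell receptor signalling components held 7 that rose and 12 that fell after 120 min with N4, and the 27 interferon-stimulated genes 4 and 13. Camera called neither list (adjusted p = 0.867 and 0.687), and the interferon-stimulated list lay above the other genes in that test although its median was -0.86. Heat shock genes rose in 7 of 16 cases and fell in 4 (camera adjusted p = 0.00594, adjusted p = 0.0643 with an estimated correlation), and housekeeping genes rose in 3 of 12 (camera adjusted p = 0.0241, adjusted p = 0.261 with an estimated correlation). Of 11 CD8 T cell identity genes 1 rose and 5 fell, and of 9 NK cell markers 4 fell (camera adjusted p = 0.867 and 0.687). The NK cell list includes genes present before co-culture, such as Ccl5 at 3910 ± 1060 and Gzma at 176 ± 37.5 TPM at 0 min. It therefore need not report NK cells. Adjusted over the list alone the counts of these lists at 120 min were the same, except 5 higher interferon-stimulated genes and 4 lower cytotoxic genes. Over all genes 556 rose and 2127 fell at 60 min and 1388 rose and 5061 fell at 120 min, with medians of -0.34 and -0.61 over all tested genes. Median-ratio scaling gave 965 higher and 1031 lower genes at 60 min and 2640 higher and 3287 lower at 120 min, while the blocked model gave 1112 higher and 4813 lower genes at 60 min and 2004 and 6359 at 120 min. With the block and median-ratio scaling 2067 rose and 2339 fell at 60 min and 3652 and 4261 at 120 min. Of the 14 B cell markers 2 fell at 120 min, 1 adjusted over the list alone (median -0.33, camera adjusted p = 0.687).

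**Figure D1:**
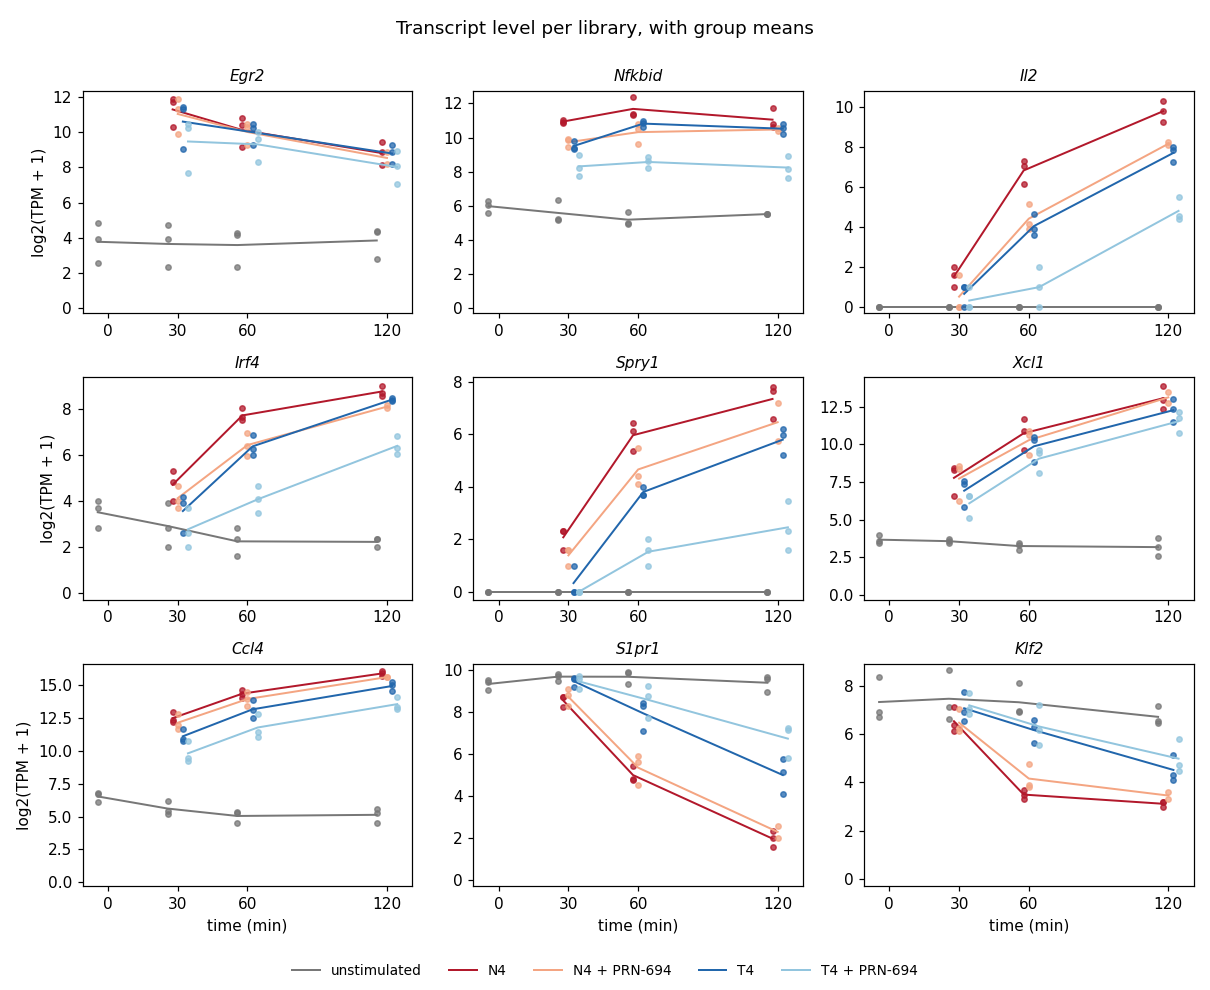
Levels of 9 panel genes as log2(TPM + 1) against time in minutes. Points are libraries and lines join group means. Colours mark unstimulated co-cultures, and N4 and T4 co-cultures without and with PRN-694. With N4 at 120 min Il2 averaged 912 TPM and S1pr1 3 TPM.

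T4 against unstimulated co-cultures asks the same of the weaker peptide. At 30 min Tnf rose to 325 ± 54 TPM, a log2 change of 6.95 ± 0.295 (adjusted p = 4.78e-19), Egr2 to 1950 ± 1220 TPM (6.96 ± 0.756, adjusted p = 7.72e-08), Ccl4 to 2290 ± 857 TPM and Fos to 1210 ± 261 TPM. Immediate early factors rose in 12 of 26 cases, NFAT-linked targets in 10 of 22, cytokines and chemokines in 8 of 23 and NF-kB targets in 5 of 24, with 0 lower in each list. Camera called these 4 lists with an estimated correlation as well (adjusted p of at most 1.8e-05), and adjusted over the list alone 16, 10, 11 and 6 members rose. By 60 min Il2 had reached 16.3 ± 6.81 TPM and Irf4 84 ± 26.7 TPM, and S1pr1 had fallen to 264 ± 112 TPM (log2 change -1.74 ± 0.409, adjusted p = 0.00651). Klf2 at 73.3 ± 23.7 against 171 ± 87.5 TPM did not pass (adjusted p = 0.181, 0.00267 in the blocked model). Quiescence and naive T cell genes held 7 lower and 2 higher members of 26 (camera adjusted p = 0.00185, adjusted p = 0.255 with an estimated correlation, 11 lower and 2 higher adjusted over the list alone). At 120 min Ccl4 stood at 31600 ± 7530 TPM, Il2 at 211 ± 53.4 TPM and Irf8, an interferon regulatory factor gene, at 969 ± 52.5 against 3 ± 1 TPM (log2 change 7.95 ± 0.448, adjusted p = 5.66e-16). S1pr1 fell to 34.7 ± 19 TPM and Klf3, a quiescence factor gene, to 5.33 ± 3.51 against 117 ± 16.2 TPM. Ribosome biogenesis genes rose in 25 of 30 cases, by a median of 1.81 (camera adjusted p = 4.69e-24, 29 adjusted over the list alone). Of the 14 B cell markers 4 fell, also adjusted over the list alone (median -1.30, camera adjusted p = 0.222, and 0.0484 with median-ratio scaling).

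In total 35 genes rose and 2 fell with T4 at 30 min, 234 and 354 at 60 min, and 1234 and 3866 at 120 min. The medians of all tested genes were -0.09, -0.23 and -0.42, and with median-ratio scaling 378 rose and 202 fell at 60 min and 2109 and 2503 at 120 min. The blocked model called 99, 3054 and 7542 genes at the 3 times. At 60 min 688 of these rose and 2366 fell, whereas with the block and median-ratio scaling 1059 rose and 998 fell. Without T4 replicate 2 at 60 min, 283 genes passed.

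N4 against T4 asks what peptide strength changes. At 30 min 10 genes were higher with N4 and 1 lower, and in the blocked model 85 and 67. Fosl1, an AP-1 subunit gene, stood at 39.7 ± 7.02 TPM with N4 and 7.33 ± 2.08 with T4, a log2 difference of 2.31 ± 0.366 (adjusted p = 0.00133). Gadd45b, a stress-response gene induced through NF-kB, stood at 524 ± 133 and 140 ± 1.15 TPM (1.87 ± 0.298, adjusted p = 0.00133), and Tnfsf14, the gene of the ligand LIGHT, at 101 ± 29.8 and 28 ± 13.1 TPM. The growth regulator gene Myc at 967 ± 347 and 253 ± 153 TPM did not pass (adjusted p = 0.0853, 1.41e-04 in the blocked model). Higher with N4 as lists were immediate early factors (median 1.13, 1 higher, 11 adjusted over the list alone), NF-kB targets (0.54, 2 higher, 9 adjusted over the list alone), NFAT-linked targets (1.13, 0 higher, 5 adjusted over the list alone) and cytokines and chemokines (0.85, 2 higher, 7 adjusted over the list alone). Their adjusted p were at most 1.05e-04 with an estimated correlation. B cell markers lay 0.88 higher by median with N4 at 30 min with no member passing (camera adjusted p = 4.83e-08, adjusted p = 0.132 with an estimated correlation). With the block and median-ratio scaling 118 genes were higher and 41 lower. Without T4 replicate 1 the count of 11 became 4, without N4 replicate 2 it became 5, and without T4 replicate 2 it became 17.

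At 60 min the cytokine gene Il17f was higher with N4, at 234 ± 109 TPM against 11 ± 8 with T4 (4.44 ± 0.782, adjusted p = 0.00171). Its relative Il17a stood at 19.7 ± 8.5 TPM with N4 and was listed at 0 with T4 (adjusted p = 8.99e-11). Il2 was higher at 118 ± 43.6 against 16.3 ± 6.81 TPM (2.77 ± 0.432, adjusted p = 4.09e-04). So were Spry1 at 64 ± 22.3 against 13 ± 1.73 TPM and Il2ra at 26.3 ± 11.2 against 7 ± 2.65 TPM. Lower with N4 were S1pr1 at 31.7 ± 8.96 against 264 ± 112 TPM (-2.94 ± 0.409, adjusted p = 6.07e-05), Klf2 at 10.3 ± 1.53 against 73.3 ± 23.7 TPM (-2.67 ± 0.476, adjusted p = 0.00183) and Ccr7 at 107 ± 53.1 against 573 ± 206 TPM. Egr2 at 1240 ± 620 and 1080 ± 410 TPM, and the orphan receptor gene Nr4a1 at 8570 ± 3500 and 6270 ± 2370 TPM, did not pass (log2 difference 0.12 ± 0.756 and 0.43 ± 0.674). Quiescence and naive T cell genes were lower in 8 of 26 cases and higher in 0 (median -0.65, camera adjusted p = 1.09e-11, 11 lower adjusted over the list alone), and activation surface molecules higher in 5 of 23 (7 adjusted over the list alone). Ribosome biogenesis genes were higher in 3 of 30 cases (median 0.38, camera adjusted p = 5.26e-14, 5 adjusted over the list alone), and these 3 lists kept their calls with an estimated correlation (adjusted p of at most 0.0418). B cell markers lay 0.83 higher by median (camera adjusted p = 1.63e-05, adjusted p = 0.204 with an estimated correlation). In all 54 genes were higher and 75 lower, and with median-ratio scaling 117 and 70. With the block 357 genes were higher and 931 lower, but with the block and median-ratio scaling 735 and 472. The count of 129 became 40 without T4 replicate 1, 43 without T4 replicate 3, 55 without N4 replicate 2 and 64 without N4 replicate 3.

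At 120 min Il17a (37 ± 8.72 against 2.67 ± 1.15 TPM, 3.39 ± 0.333, adjusted p = 2.89e-08), Il17f (493 ± 295 against 51.7 ± 33.3 TPM) and Il2 (912 ± 322 against 211 ± 53.4 TPM, 2.08 ± 0.432, adjusted p = 0.00351) were again higher with N4. Zbtb32, a transcriptional repressor gene, was higher at 10 ± 2.65 against 1.33 ± 0.577 TPM. Lower with N4 were S1pr1 at 3 ± 1 against 34.7 ± 19 TPM (-3.03 ± 0.409, adjusted p = 1.05e-05), Ifngr2, an interferon-gamma receptor chain gene, at 5.33 ± 2.08 against 35 ± 16.1 TPM, and Tcf7, a transcription factor gene of naive and memory T cells, at 14.3 ± 4.51 against 81.3 ± 45.7 TPM. Egr2 differed by 0.02 ± 0.756. Ribosome biogenesis genes were higher with N4 in 5 of 30 cases (median 0.44, camera adjusted p = 1.26e-15, 7 adjusted over the list alone), with an adjusted p of 0.0163 with an estimated correlation. Quiescence and naive T cell genes were lower in 9 of 26 cases (median -0.79, camera adjusted p = 4.96e-08, adjusted p = 0.0635 with an estimated correlation, 14 adjusted over the list alone), and interferon-stimulated genes in 4 of 27 (median -0.86, camera adjusted p = 1.07e-04, adjusted p = 0.287 with an estimated correlation, 8 adjusted over the list alone). B cell markers lay 0.86 higher by median and the 4 erythroid markers 1.24 higher, with no member passing (camera adjusted p = 3.27e-06 and 0.00729, adjusted p = 0.166 and 0.171 with an estimated correlation). In all 59 genes were higher and 357 lower, and with median-ratio scaling 154 and 270. With the block 358 genes were higher and 2260 lower, and with the block and median-ratio scaling 1185 and 1331. The count of 416 became 173 without T4 replicate 1, 176 without T4 replicate 3, 190 without N4 replicate 2 and 239 without N4 replicate 3.

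PRN-694 with N4 asks which transcripts the inhibitor changes in cultures with the strong peptide. No unstimulated culture held PRN-694. An effect on the peptide response therefore cannot be told apart from an effect of the inhibitor without peptide, for N4 or for T4. At 30 min 0 of 11757 genes passed in limma, with 181 at an unadjusted p below 0.05 and 8 (2 higher, 6 lower) in the blocked model. Nfkbia, the gene of the NF-kB inhibitor IkB-alpha, stood at 987 ± 426 TPM with PRN-694 and 2600 ± 803 without (log2 change -1.45 ± 0.417, adjusted p = 1, 6.57e-08 in the blocked model), and Nfkbid at 854 ± 138 and 1960 ± 101 TPM. As lists, NF-kB targets (median -0.34, 5 lower adjusted over the list alone) and immediate early factors (median -0.62, 3 lower adjusted over the list alone) were lower with PRN-694 (camera adjusted p = 9.44e-18 for each, adjusted p = 2.28e-04 and 2.44e-04 with an estimated correlation). Egr2 at 2440 ± 1430 and 2790 ± 1340 TPM did not pass. Without N4 with PRN-694 replicate 2 the count was 1, and without N4 replicate 2 or 3 it was 2.

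At 60 min 9 genes fell with PRN-694 and 0 rose. Il2 fell from 118 ± 43.6 to 22 ± 11.4 TPM, a log2 change of -2.40 ± 0.432 (adjusted p = 0.00832), and Nfkbie, the gene of IkB-epsilon, from 76 ± 2.65 to 29 ± 4 TPM (-1.37 ± 0.237, adjusted p = 0.00571). F3, the tissue factor gene, fell from 7 ± 2 to 1.33 ± 1.53 TPM, and Stx11, a syntaxin gene of granule release, from 16 ± 6.08 to 4.67 ± 1.53 TPM. Irf4 at 88.3 ± 31.3 and 211 ± 41 TPM did not pass (adjusted p = 1, 0.0513 in the blocked model). NF-kB targets were lower as a list (median -0.58, 1 passing, 7 adjusted over the list alone, camera adjusted p = 1.13e-26, adjusted p = 6.25e-06 with an estimated correlation), and so were cytokines and chemokines (median -0.46, 1 passing, 3 adjusted over the list alone, adjusted p = 0.0258 with an estimated correlation). In the blocked model 32 genes rose and 95 fell. Without N4 with PRN-694 replicate 1 the count was 3, and without replicate 3 of that group it was 2.

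With 2 libraries of N4 with PRN-694 at 120 min, 6 genes rose and 9 fell. Zbtb32 fell from 10 ± 2.65 to 1.5 ± 0.707 TPM (n = 2 with PRN-694; log2 change -2.14 ± 0.311, limma adjusted p = 2.21e-04), and Ncoa7, a nuclear receptor coactivator gene, rose from 2.33 ± 1.53 to 8.5 ± 0.707 TPM (n = 2 with PRN-694; 1.61 ± 0.321, limma adjusted p = 0.0158). The other named genes that fell were Trp53inp1, a stress gene induced by p53, Sytl3, a vesicle transport gene, Tpm1, a tropomyosin gene, and Srxn1, an antioxidant enzyme gene, by 1.56, 1.16, 1.05 and 1.03 on the log2 scale. Il2 at 283 ± 21.2 (n = 2) and 912 ± 322 TPM did not pass (-1.63 ± 0.483, limma adjusted p = 0.341, 0.00662 in the blocked model). Camera called ribosome biogenesis (median -0.30, adjusted p = 1.72e-07) and NF-kB targets (-0.16, adjusted p = 0.0034) lower, but with an estimated correlation the adjusted p were 0.322 and 0.462, and no member of either passed, over all genes or adjusted over the list alone. Without the block these medians, and the interaction at 120 min, include N4 replicate 1, which has no partner with PRN-694. Within the 2 pairs the mean changes of these lists were -0.155 ± 0.025 and -0.035 ± 0.096 (SD). With median-ratio scaling 17 genes rose and 20 fell, and the blocked model called 414, of which 356 rose, but with the block and median-ratio scaling 169 rose and 170 fell. Without N4 with PRN-694 replicate 2 the count of 15 became 49.

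PRN-694 with T4 asks the same of the weaker peptide. At 30 min 3 genes fell and 0 rose: Gadd45b from 140 ± 1.15 to 48 ± 22.7 TPM (log2 change -1.62 ± 0.298, adjusted p = 0.0227), Tnf from 325 ± 54 to 112 ± 43 TPM (-1.58 ± 0.295, adjusted p = 0.0227), and Lif, a cytokine gene of the interleukin-6 family, from 3 ± 1 to 0.333 ± 0.577 TPM. Immediate early factors (median -0.62, 0 passing, 3 adjusted over the list alone), NFAT-linked targets (-0.71, 1, 3 adjusted over the list alone), cytokines and chemokines (-0.34, 2, 5 adjusted over the list alone) and NF-kB targets (-0.16, 2, 3 adjusted over the list alone) were lower as lists, with adjusted p between 1.28e-04 and 0.00103 with an estimated correlation. In the blocked model 10 genes passed, each lower. Without T4 replicate 1 the count was 1, and without T4 replicate 2, T4 replicate 3 or T4 with PRN-694 replicate 3 it was 0 in limma, where 114 genes in the full set had an unadjusted p below 0.05.

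At 60 min 17 genes fell with PRN-694 and 0 rose. Il2 fell from 16.3 ± 6.81 to 1.33 ± 1.53 TPM (-3.05 ± 0.432, adjusted p = 1.56e-04) and Gadd45b from 332 ± 41.8 to 57.3 ± 19.1 TPM (-2.55 ± 0.298, adjusted p = 4.53e-06). Irf4 fell from 84 ± 26.7 to 16.7 ± 7.02 TPM (-2.30 ± 0.443, adjusted p = 0.0112), Spry1 from 13 ± 1.73 to 2 ± 1 TPM, Nfkbid from 1810 ± 192 to 385 ± 82.8 TPM and Tnf from 422 ± 100 to 139 ± 38.6 TPM. Egr2 (-0.69 ± 0.756), Egr1, another early growth response gene (-0.56 ± 0.413), and Nr4a1 (-0.55 ± 0.674) did not pass in either model. The 26 immediate early factors were lower as a list, by a mean of -0.812 ± 0.057 (SD, 3 pairs; median -0.76, 1 passing, 7 adjusted over the list alone, camera adjusted p = 3.12e-19). The adjusted p was 8.24e-05 with an estimated correlation. Of the 24 NF-kB targets 5 fell and 0 rose (median -0.93, camera adjusted p = 1.31e-50, 16 adjusted over the list alone). Of 23 cytokines and chemokines 4 fell (median -1.25, 9 adjusted over the list alone) and of 22 NFAT-linked targets 3 fell (median -0.92, 8 adjusted over the list alone). These 3 lists had adjusted p of at most 8.14e-06 with an estimated correlation. CD4 T cell markers, a list that includes the activation gene Cd40lg (CD40 ligand), were lower by a median of -0.21 with 0 of 6 members passing, 1 adjusted over the list alone (camera adjusted p = 0.0115, adjusted p = 0.025 with an estimated correlation). The blocked model called 14 higher and 82 lower genes. Without T4 replicate 2 the count was 5, without T4 with PRN-694 replicate 1 it was 6, and without replicate 3 of that group it was 7.

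At 120 min 148 genes rose and 208 fell. Spry1 fell from 56.7 ± 18.9 to 5.33 ± 4.16 TPM (-3.34 ± 0.397, adjusted p = 2.47e-06) and Il2 from 211 ± 53.4 to 28.7 ± 13.3 TPM (-2.89 ± 0.432, adjusted p = 8.99e-05). Gadd45b fell from 465 ± 24.4 to 81.3 ± 15.7 TPM (-2.52 ± 0.298, adjusted p = 2.47e-06), Irf4 from 336 ± 16.4 to 84.7 ± 23.7 TPM (-2.01 ± 0.443, adjusted p = 0.00646) and Il2ra from 123 ± 28.1 to 42 ± 19.5 TPM. Sit1, the gene of an adaptor that dampens receptor signalling, rose from 12 ± 1 to 56.7 ± 6.43 TPM (2.15 ± 0.313, adjusted p = 7.26e-05), and S1pr1 from 34.7 ± 19 to 115 ± 52.4 TPM (1.73 ± 0.409, adjusted p = 0.012). Of 30 ribosome biogenesis genes 11 fell and 0 rose (median -0.92, camera adjusted p = 1.53e-27, 18 adjusted over the list alone). They included Ncl, the nucleolin gene, which fell from 328 ± 37.2 to 162 ± 17.8 TPM. The fixed list also held Srm, the gene of spermidine synthase, a polyamine enzyme, which fell from 114 ± 21.9 to 31 ± 9.54 TPM. NF-kB targets fell in 7 of 24 cases (median -1.03, 18 adjusted over the list alone), NFAT-linked targets in 5 of 22 (median -1.05, 9 adjusted over the list alone), and cytokines and chemokines in 5 of 23 (median -1.30, 14 lower and 1 higher adjusted over the list alone). Effector differentiation transcription factors fell in 1 of 18 (median -0.51, 4 adjusted over the list alone). Camera called these 5 lists with an estimated correlation as well (adjusted p of at most 0.00412). Immediate early factors fell in 3 of 26 (median -0.73, 7 adjusted over the list alone, camera adjusted p = 4.67e-07), with an adjusted p of 0.0184 with an estimated correlation and 0.0935 with the block as well. Ifng, the interferon-gamma gene, at 362 ± 197 and 1510 ± 578 TPM did not pass (-2.11 ± 0.643, adjusted p = 0.0651, 1.08e-04 in the blocked model), nor did Ccl4 at 12400 ± 4360 and 31600 ± 7530 TPM (adjusted p = 0.0676, 1.73e-04 in the blocked model). The kinase genes Itk at 445 ± 122 and 480 ± 124 TPM and Txk at 122 ± 43.6 and 95.7 ± 27.7 TPM did not pass. Myeloid and dendritic cell, NK cell and erythroid markers held no member that passed (camera adjusted p = 0.996, 0.996 and 0.618), nor did CD4 T cell markers, with a median of -0.36 (camera adjusted p = 0.062, adjusted p = 0.0869 with an estimated correlation). The myeloid and NK cell lists include genes present before co-culture, such as Cst3 at 242 ± 44.3 and Ccl5 at 3910 ± 1060 TPM at 0 min. Those lists therefore need not report other cells. Median-ratio scaling gave 191 higher and 329 lower genes, the blocked model 1322 and 1025, and both together 1152 and 1341. The count of 356 became 135 without T4 replicate 2 and 164 without T4 with PRN-694 replicate 3.

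**Figure D2:**
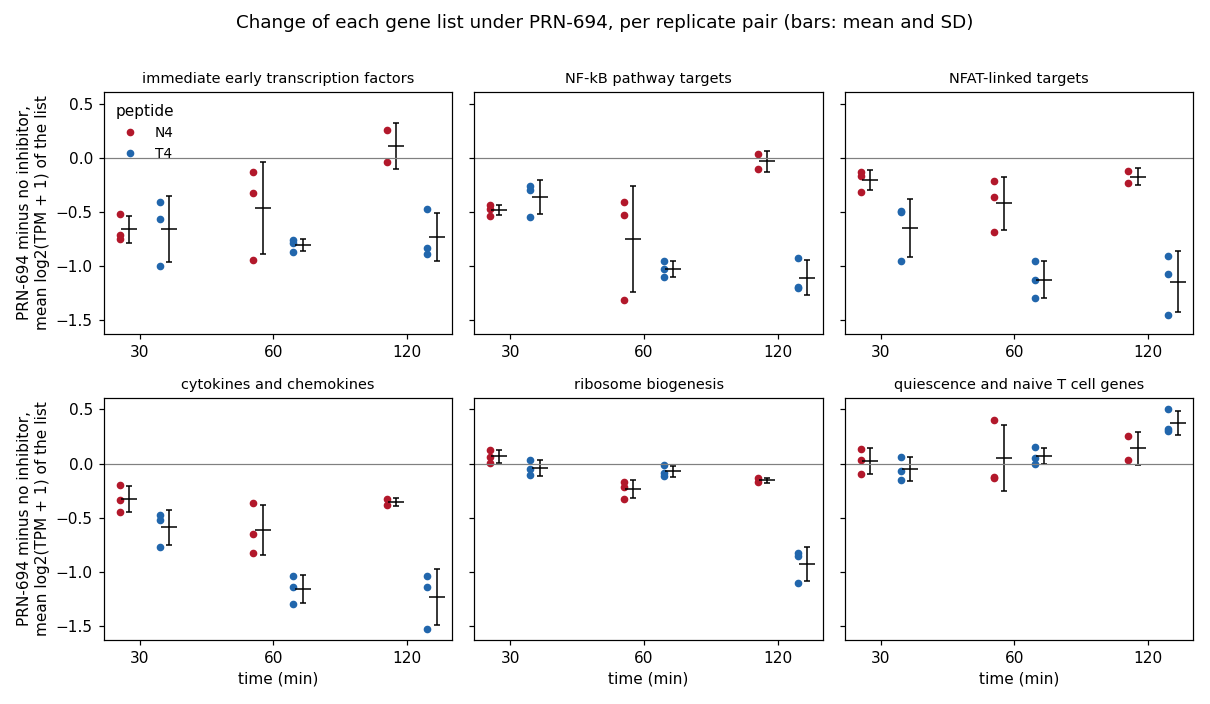
Mean log2(TPM + 1) of 6 gene lists with PRN-694 less that without, per replicate pair, for N4 and T4 at 30, 60 and 120 min. Points are pairs and bars are means with SD. At 120 min the mean change of ribosome biogenesis genes was -0.929 ± 0.155 with T4 (3 pairs) and -0.155 ± 0.025 with N4 (2 pairs).

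The interaction asks whether PRN-694 acted differently with T4 than with N4. In limma 0 genes passed at 30 and 60 min (110 and 108 at an unadjusted p below 0.05), also in the blocked model (305 and 366). At 120 min 6 genes passed, 2 with a more positive effect with T4 and 4 with a more negative effect. Pus7, a pseudouridine synthase gene, stood at 15.7 TPM with PRN-694 and 49.3 without it in T4 cultures, and at 57.5 (n = 2) and 67 TPM in N4 cultures (log2 difference -1.40 ± 0.281, adjusted p = 0.033). Il12rb1, an interleukin-12 receptor chain gene, stood at 2.33 and 6.67 TPM in T4 cultures and at 11.5 (n = 2) and 5 TPM in N4 cultures (-2.21 ± 0.443, adjusted p = 0.033). The other 4 genes, Tex15, Map1b, Lrrc32 and Mir8113, had no group above 5 TPM, and Tex15 and Map1b were listed at 1 in each N4 library and at 0 in the other 3 groups; these 4 were named after their values were seen. Spry1 (-2.45 ± 0.596, adjusted p = 0.138) and Gadd45b (-2.01 ± 0.447, adjusted p = 0.0783) did not pass over all genes. Both passed in the blocked model (0.0109 and 0.0101) and adjusted over the list alone (0.00334 and 0.00138). For a gene in more than 1 list, the list-alone value is the smallest over its lists.

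As lists at 120 min, NF-kB targets differed by a median of -0.97 (camera adjusted p = 3.61e-12, 3 lower adjusted over the list alone), cytokines and chemokines by -1.06 (adjusted p = 1.09e-08, 1) and NFAT-linked targets by -1.03 (adjusted p = 1.98e-08, 0). Ribosome biogenesis differed by -0.62 (adjusted p = 7.85e-12, 2), nutrient uptake and metabolism by -0.49 (adjusted p = 1.01e-05, 2) and effector differentiation factors by -0.50 (adjusted p = 0.00287, 0), each more negative with T4. With an estimated correlation the adjusted p were between 0.00279 and 0.027. With the block and an estimated correlation, NF-kB targets (0.0296) and ribosome biogenesis (0.0235) passed, and NFAT-linked targets (0.143), cytokines and chemokines (0.085), nutrient uptake (0.085) and effector factors (0.085) did not. At 60 min NFAT-linked targets differed by -0.70 (camera adjusted p = 9.11e-11, adjusted p = 0.0204 with an estimated correlation, 0.0795 with the block and an estimated correlation). The blocked model called 49 genes with a more positive and 159 with a more negative effect with T4 at 120 min, but with the block and median-ratio scaling 120 and 123. With median-ratio scaling alone 12 passed. The count of 6 became 3 without T4 with PRN-694 replicate 1, 34 without N4 with PRN-694 replicate 2 and 10 without N4 with PRN-694 replicate 3. The counts at 30 and 60 min became 1 without N4 replicate 2 and without N4 replicate 1, respectively.

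Genes induced by one peptide were also followed under PRN-694 with the other. Each list was chosen on libraries of this series other than those of the contrast in which it was tested. Of the 108 genes induced by N4 at 30 min, 94 (87%) had a negative change with PRN-694 in T4 cultures (median -0.39), as did 471 of 556 (84.7%, median -0.36) at 60 min and 1252 of 1388 (90.2%, median -0.53) at 120 min. With an estimated correlation the adjusted p of these 3 lists were at most 1.6e-05, and at 120 min 192 of the 1388 fell and 3 rose. Of the genes induced by T4, 29 of 35 (82.9%, median -0.45) at 30 min and 167 of 234 (71.4%, median -0.25) at 60 min had a negative change with PRN-694 in N4 cultures (adjusted p = 1.19e-04 and 0.0114 with an estimated correlation). At 120 min 690 of 1234 (55.9%) did, with a median of -0.04 (camera adjusted p = 2.08e-04, adjusted p = 0.207 with an estimated correlation). In the blocked model, which called more genes induced, the medians of the N4-induced lists were -0.20, -0.19 and -0.43 at the 3 times, and with an estimated correlation these passed (adjusted p of at most 0.00443). Those of the T4-induced lists were -0.24, -0.09 and 0.02, and with an estimated correlation only the list of 30 min passed (adjusted p = 0.0102, against 0.179 at 60 and at 120 min).

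Some of these medians moved by more than 1.5 times with 1 library or 1 replicate number left out. For N4-induced genes the median at 30 min became -0.22 without T4 with PRN-694 replicate 3 and -0.62 without replicate 2 in every group, and at 60 min -0.57 without replicate 2. For T4-induced genes the median at 60 min became -0.11 without N4 with PRN-694 replicate 1, -0.12 without replicate 1 in every group and -0.53 without replicate 2. At 120 min it became 0.04 without N4 replicate 1, -0.11 without N4 replicate 3, -0.01 without N4 with PRN-694 replicate 3, -0.08 without T4 replicate 3 and -0.07 without the unstimulated replicate 1. Without replicates 1, 2 and 3 in turn it was 0.04, -0.02 and -0.12.

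Unstimulated co-cultures against 0 min set cells after culture with peptide-free splenocytes against cells before it. No group was cultured without splenocytes, so effects of time, of culture and of the splenocytes cannot be told apart. Fos fell from 116 ± 28 TPM at 0 min to 31.3 ± 7.23 at 30 min (log2 change -1.86 ± 0.313, adjusted p = 0.00347), 12.3 ± 3.21 at 60 min (-3.14 ± 0.313, adjusted p = 7.37e-08) and 9 ± 3.61 at 120 min (-3.60 ± 0.313, adjusted p = 2.03e-09). Jun, another AP-1 subunit gene, fell from 59 ± 24.6 to 8 ± 3.61 TPM at 60 min, and Cd69 from 1170 ± 731 to 252 ± 129 TPM. Itk rose from 258 ± 34.3 to 806 ± 110 TPM at 60 min (1.64 ± 0.295, adjusted p = 7.76e-04) and stood at 805 ± 136 TPM at 120 min. Spsb1, a ubiquitin ligase adaptor gene, rose from 2 ± 1 to 42 ± 1 TPM at 60 min. H2-Aa, a class II MHC gene of antigen-presenting cells, was listed at 0 in each 0 min library and stood at 15.7 ± 12.6, 20.7 ± 14.5 and 31.7 ± 23.1 TPM at 30, 60 and 120 min (adjusted p = 0.0229, 7.53e-04 and 4.77e-05). B cell markers rose in 1, 4 and 5 of 14 cases at the 3 times, and in 7, 7 and 9 adjusted over the list alone (camera adjusted p = 2.54e-08, 4.67e-06 and 6.27e-06). With an estimated correlation the adjusted p were 0.44, 0.349 and 0.32. Immediate early factors fell in 1, 4 and 5 of 26 cases (median -0.77 at 120 min, camera adjusted p = 1.09e-06, adjusted p = 0.101 with an estimated correlation), and in 2, 6 and 6 adjusted over the list alone. CD8 T cell identity genes fell in 2 of 11 cases at 120 min, also adjusted over the list alone (camera adjusted p = 8.21e-04, adjusted p = 0.32 with an estimated correlation). The CD8 beta chain gene Cd8b1 stood at 1320 ± 113 against 2370 ± 469 TPM (adjusted p = 0.00965). S1pr1 did not pass at 120 min, at 686 ± 167 against 651 ± 102 TPM.

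In all 14 genes rose and 3 fell in unstimulated cultures at 30 min, 203 and 133 at 60 min, and 384 and 288 at 120 min, while with median-ratio scaling 26 and 11, 208 and 229, and 336 and 466 did. With the block 301 rose and 228 fell at 30 min, 1222 and 989 at 60 min and 1843 and 1229 at 120 min, and with the block and median-ratio scaling 326 and 219, 1063 and 1189, and 1368 and 1590. At 30 min the count of 17 became 5 without the unstimulated replicate 1 of that time, 3 without its replicate 2 and 37 without the 0 min replicate 3. At 60 min the count of 336 became 223 without the 0 min replicate 2, 209 without the unstimulated replicate 2 and 188 without its replicate 3. At 120 min the count of 672 became 442 without the 0 min replicate 1, 425 without the 0 min replicate 2, 333 without the unstimulated replicate 1 and 434 without its replicate 3.

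**Figure D3:**
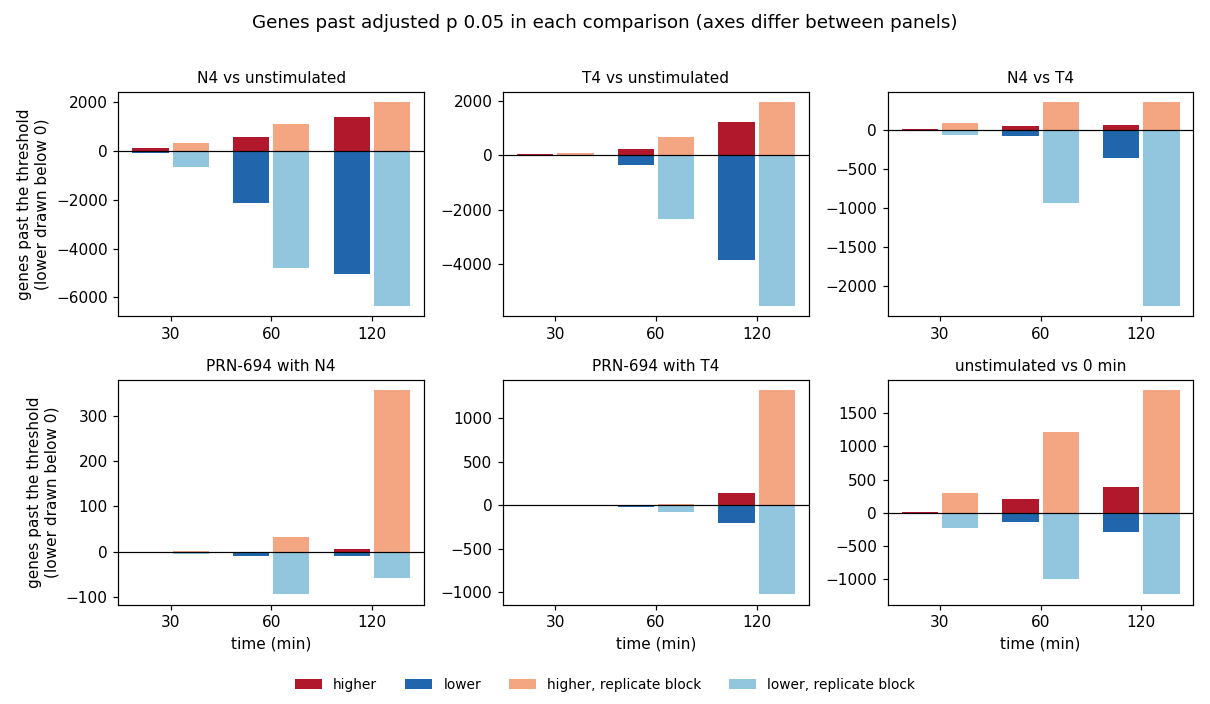
Genes higher and lower in the comparisons by time, in the model without and with the replicate number as a block; the vertical axes differ between panels. With N4 against unstimulated cells at 120 min 5061 genes fell and 1388 rose without the block.

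On mm10 (GRCm38), the annotation places the protein-coding genes Il2 on chromosome 3 from 37120523 to 37125959, Spry1 on chromosome 3 from 37639947 to 37644598, S1pr1 on chromosome 3 from 115710433 to 115715072, Irf4 on chromosome 13 from 30749226 to 30766976, Nfkbid on chromosome 7 from 30421732 to 30428746 and Gadd45b on chromosome 10 from 80930073 to 80932204. Egr2 lies on chromosome 10 from 67535475 to 67542188, Tnf on chromosome 17 from 35199381 to 35202007, Ccl4 on chromosome 11 from 83662584 to 83664683, Itk on chromosome 11 from 46325150 to 46389515 and Txk on chromosome 5 from 72695978 to 72752777.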

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

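The interaction and gene list tests below were fixed earlier, while the tests of the 3 patterns and the readings of the splits were chosen only after the results were seen.

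The effect of PRN-694 differed between T4 and N4 cultures at 120 min for 6 genes in the interaction test, with log2 differences (T4 less N4) of -2.21 for the receptor chain gene Il12rb1 and -1.40 for the pseudouridine synthase gene Pus7. Among gene lists at 120 min the inhibitor's effect was more negative with T4 by a median of -0.97 for NF-kB targets, -1.03 for NFAT-linked targets, -1.06 for cytokines and chemokines, -0.50 for effector differentiation factors, -0.62 for ribosome biogenesis and -0.49 for nutrient uptake and metabolism. At 60 min it was more negative by -0.70 for NFAT-linked targets. These 7 list results also passed with an estimated correlation, and with the replicate block and an estimated correlation only NF-kB targets (adjusted p = 0.0296, the highest over its alternatives) and ribosome biogenesis at 120 min passed (adjusted p = 0.0235, against 0.024 with the estimated correlation alone). The call of Il12rb1 ended with a pseudocount of 0.1 (adjusted p = 0.066) and those of both genes with only the groups compared (adjusted p = 0.375 and 0.807).

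After 120 min with N4 more genes fell (5061) than rose (1388). Rounding of low values cannot be the whole cause, since 2752 genes fell and 997 rose among the 6317 with a mean of at least 10 TPM. A fixed total may account for part of it. The genes that rose gained 253066 TPM, and the summed TPM of the rest changed by -0.463 ± 0.045 on the log2 scale (SD, 3 pairs). The median over all tested genes was -0.616 ± 0.0538. With a fixed total the summed change follows from the gain whatever the cause, and it is a sum set against a median. The gap of -0.153 ± 0.0987 therefore decides nothing. Leaving out all genes with a positive change gave -0.723 ± 0.112 for the rest. The fixed total and a real loss of transcripts after peptide cannot be told apart without an external standard. After the gain was removed, 2049 genes rose and 3697 fell.

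At 120 min 356 genes passed under PRN-694 with T4 and 15 with N4, and the interaction passed for 6, in a test that recovered 0% of simulated changes of 1 on the log2 scale without the block and 55.2% with it. The smaller number of N4 libraries with PRN-694 cannot be the whole cause: with replicate 1 left out of every group, 197 genes passed with T4 and 13 with N4. The interaction then passed for 23 genes, and in the blocked model for 753, against 208 there with all replicates. Nor can 1 library be, since with 1 library left out the lowest count with T4 was 135 (without T4 replicate 2) and the highest with N4 was 49 (without N4 with PRN-694 replicate 2). Without replicate 2 in every group N4 with PRN-694 held 1 library, and the counts with T4 and with N4 drew near each other. The 983 genes that N4 induced in that fit changed with PRN-694 by medians of -0.493 and -0.752 in the T4 pairs, against 0 in the 1 N4 pair left. Of 13 fixed lists of T cell biology, 8 had both T4 pairs below that N4 pair. With 1 N4 pair there is no spread to judge by, so replicate 2 as the whole cause stays open. A different action of PRN-694 with each peptide, which the groups name, stays open as a hypothesis.

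Class II MHC and B cell transcripts appeared in the co-cultured OT-I libraries, with H2-Aa listed at 0 in each 0 min library and at 15.7 ± 12.6 TPM without peptide, 36 ± 28.1 with N4 and 13.7 ± 3.51 with T4 after 30 min (SD, n = 3 each). After group and replicate number were removed, the class II genes H2-Aa, H2-Ab1 and H2-Eb1 varied with the B cell genes Cd79a, Cd19 and Ly6d over 44 libraries (Pearson r = 0.908, Spearman rho = 0.889, permutation p = 1e-05 for each, the smallest that 100000 permutations can give). The r was 0.888 without the 2 libraries farthest from the median, and 0.862, 0.874 and 0.945 within replicates 1, 2 and 3. The 3 B cell genes were picked from the tested markers, so the r covers only the genes named. Among the markers left out, Cd79b stood at 30 ± 12.5 TPM at 0 min and at 16.3 ± 5.13 without peptide after 30 min. Blk stood at 2.33 TPM in both groups. RNA of the presenting splenocytes may be the source of the genes that varied together. The sort on CD8a and CD45.2 was set to leave such cells out, but how many it let through is not known here. Before co-culture 4 of the 14 tested B cell markers had a mean of at least 1 TPM and 6 a mean of 0. Cd74 stood at 3 ± 2.65 TPM at 0 min and at 20.7 ± 8.62 without peptide and 51.3 ± 31 with N4 after 30 min (SD, n = 3 each), and no biological explanation was tested.

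Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. The real count against the highest of the other splits was 179 against 1 for N4 and 37 against 0 for T4 over unstimulated cells at 30 min, 2683 against 1 and 588 against 0 at 60 min, and 6449 against 2 and 5100 against 0 at 120 min. For N4 against T4 it was 11 against 3, 129 against 3 and 416 against 1. For PRN-694 with N4 it was 0 in limma (181 genes at an unadjusted p under 0.05, and 8 adjusted with the block) against 3 at 30 min and 9 against 2 at 60 min. For PRN-694 with T4 it was 3 against 1, 17 against 0 and 356 against 6. For unstimulated cells over 0 min it was 17 against 2, 336 against 3 and 672 against 1. Among the 4 splits that part all 3 replicate pairs, the real one gave the most genes except for PRN-694 with N4 at 30 min, where another gave 3; the other 6 splits part 1 pair each. In the interaction at 30 and 60 min the real count was 0 in limma with and without the block (110 and 108 genes at an unadjusted p under 0.05). The highest of the others among 100 drawn splits were 3 and 25. Where the real count was 0, any split gives as many (here 10 of 10 and 100 of 100), so these 3 comparisons with other splits say nothing about chance.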

How the results depend on the processing

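The alternatives were planned, except the block with median-ratio scaling and the block with an estimated correlation, which were chosen after seeing the data. Where a count moved by more than 1.5 times, or a direction changed, the cause was not tested.

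The replicate number pairs the samples, and with the replicate block the counts rose to 975, 5925 (N4 against unstimulated, 30 and 60 min), 99, 3054 (T4 against unstimulated, 30 and 60 min), 152, 1288, 2618 (N4 against T4 at 30, 60 and 120 min), 8, 127, 414 (PRN-694 with N4), 10, 96, 2347 (PRN-694 with T4), 208 (interaction, 120 min), and 529, 2211 and 3072 (unstimulated over 0 min). With the block and median-ratio scaling the same comparisons gave 800, 4406, 134, 2057, 159, 1207, 2516, 17, 145, 339, 12, 107, 2493, 243, 545, 2252 and 2958. The median of T4-induced genes under PRN-694 with N4 at 120 min turned from -0.04 to 0.023 with the block, also with an estimated correlation, and its call ended with an estimated correlation alone (-0.042). At 60 min that median was -0.093 and no longer passed with the block and an estimated correlation.

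Fitting only the groups compared left limma counts of 54 and 1540 for N4 and 13 and 130 for T4 over unstimulated cells at 30 and 60 min, 2, 0 and 88 for N4 against T4, 0 and 128 for PRN-694 with N4 at 60 and 120 min, 0, 0 and 75 for PRN-694 with T4, 0 for the interaction at 120 min, and 1, 2 and 37 for unstimulated cells over 0 min. At an unadjusted p under 0.05 the counts of 0 became 816 (N4 against T4, 60 min), 186 (PRN-694 with N4, 60 min), 68 and 195 (PRN-694 with T4, 30 and 60 min) and 413 (interaction). With a pseudocount of 0.1 the counts were 731 (N4 against T4, 120 min), 36 (interaction, 120 min), 4 and 51 (PRN-694 with N4, 60 and 120 min) and 26 (unstimulated, 30 min). With a pseudocount of 5 they were 17 and 213 (N4 against T4, 30 and 120 min), 16 (interaction, 120 min), 16 and 28 (PRN-694 with N4, 60 and 120 min) and 28 (unstimulated, 30 min). Median-ratio scaling gave 26 (N4 against T4, 30 min), 12 (interaction, 120 min), 37 (PRN-694 with N4, 120 min) and 37 (unstimulated, 30 min), and no filter 29 for the last.

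Leaving out 1 library or 1 replicate number gave ranges of 66 to 209, 1073 to 2675 (N4 against unstimulated, 30 and 60 min), 17 to 44, 147 to 682, 3068 to 5643 (T4 against unstimulated), 1 to 17, 35 to 170, 113 to 466 (N4 against T4), 0 to 2, 2 to 14, 5 to 49 (PRN-694 with N4), 0 to 3, 3 to 20, 53 to 497 (PRN-694 with T4), 0 to 1, 0 to 1, 3 to 34 (interaction), and 3 to 56, 50 to 440 and 185 to 877 (unstimulated over 0 min). The range was -0.116 to 0.042 for T4-induced genes under PRN-694 with N4 at 120 min, where replicate 1 left out gave 0.036. Where 1 library was left in a group, it was assumed to vary like the others.

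Of the 125 gene results named, 59 lost their call when only the groups compared were fitted, 13 with a pseudocount of 0.1, 5 with a pseudocount of 5 and 2 with median-ratio scaling, and 8 gained one with the block. Of the 82 list results, 20 lost their call with an estimated correlation and 27 with the block and an estimated correlation. Apart from the T4-induced list above, which had passed, the directions that turned belonged to results that did not pass before or after: S1pr1 in unstimulated cells at 120 min with median-ratio scaling (-0.057), and, as the test's direction, CD8 T cell identity (-0.999 with the block) and receptor signalling components (-0.95 with only the groups compared) after N4 at 120 min, and under PRN-694 with T4 at 120 min myeloid markers (0 with only the groups compared) and NK cell markers (0.091 with a pseudocount of 0.1 and with the block, 0 with no filter, 0.029 with median-ratio scaling). B cell markers after N4 at 120 min turned likewise with median-ratio scaling (-0.12).

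Depth could not be examined, since the files hold no counts. Of simulated changes of 1 on the log2 scale, 41.8% were recovered for PRN-694 with T4 at 120 min and 28.4% for PRN-694 with N4, and in the blocked model 97% and 77.6%. For the interaction at 120 min 0% were recovered by limma without the block and 55.2% with it. Each of these rates rests on 67 genes changed in simulated values. They need not hold for weakly expressed genes or where many genes change.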

Other observations

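The selection of genes in this part and its tests were chosen after the values were seen.

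Genes with zinc-finger symbols (328 tested genes named Zfp, Zkscan, Zscan or Zbtb with a number) had a median log2 change of -0.67 after 60 min with N4, against -0.34 for the other tested genes. The difference did not pass in camera with an estimated correlation (p = 0.116). The set was taken by symbol alone, and its members need not be transcription factors. Of the 328 genes, 120 (36.6%) fell and 8 rose, against 17.6% that fell among the other genes. Zkscan14 fell from 74.7 ± 24.6 to 3.67 ± 2.89 TPM (SD, n = 3 each; limma adjusted p = 8.61e-10). With median-ratio scaling the median was -0.37 against -0.03, and 84 fell. Camera gave p = 1.82e-05 at its preset correlation and p = 0.000259 with the replicate block, on a set chosen from the same values. With T4 at 60 min the median was -0.39 against -0.22, with 39 lower, and at 120 min with N4 it was -0.88 against -0.60, with 179 lower.

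The haemoglobin gene Hba-a2 stood at 3.33 ± 2.52 TPM (SD, n = 3) at 0 min and after 30 min at 47.3 ± 75.1 TPM without peptide, 76 ± 107 with N4 and 24 ± 28.4 with T4 (SD, n = 3 each).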
